A study of Mus musculus with 18 samples.

How the data were processed

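RNA of spinal cord microglia was sequenced in 18 libraries from female mice labelled wild type, described by the labels as microglia RNA from Tmem119-Cre:RiboTag mice. Per the labels, 6 libraries came from EAE mice with control treatment (replicates 1, 2, 9, 10, 17 and 18), 6 from healthy mice with control treatment (3, 4, 11, 12, 19 and 20) and 6 from EAE mice with metformin (5, 6, 13, 14, 21 and 22). The labels name the molecule as total RNA and do not describe a pull-down of tagged ribosomes, and they give no dose or time. Per the submitters' processing notes, RNA was isolated with a column kit from Zymo Research (Direct-zol), libraries were made with the KAPA Stranded RNA-Seq kit (mRNA enrichment, strand selection and PCR), and reads were handled with bcl2fastq 2.17, FastQC and Trimmomatic and set against mm10. The aligner, the counting tool and the annotation are not given in the sources used here. Per the file headers and the values, the authors' table holds counts per gene as whole numbers for 39017 Ensembl genes.

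Symbols and positions came from GENCODE M21 (GRCm38, the same assembly as mm10), which gave a symbol for 37607 genes and a position for 37693, and 1410 genes had no symbol. At 0 in all 18 libraries were 14191 genes, among them 4290 of 21303 protein-coding genes. Library totals were 46.2 to 58.3 M (M, mega; mean 52.9 ± 4.42 M in control EAE, 50.8 ± 2.38 M in healthy and 50.5 ± 3.61 M in metformin libraries, SD, n = 6 each). Replicates were checked for duplicates: the lowest chi-square per degree of freedom between 2 of them was 15.5. Counts are of PCR-amplified reads without molecular identifiers, so intervals and floors that rest on counts cover counting error only.

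Genes were filtered with filterByExpr (minimum count 10, minimum total count 15), which left 16740. All 18 libraries entered 1 edgeR 4.0.16 fit (TMM scaling, robust quasi-likelihood F test, R 4.3.3) with group means and no covariate, at Benjamini-Hochberg adjusted p under 0.05. The prior degrees of freedom were 5.28 and the common dispersion was 0.0598 (biological coefficient of variation 0.245). The standard error of a log2 change was its size divided by the square root of F. The comparisons were control EAE against healthy, metformin EAE against control EAE, and metformin EAE against healthy. The labels pair no libraries, so no block was used, and the unit of the edgeR and exact permutation tests was the library. Later tests of RNA carried over into metformin replicate 22 and of gene length drew genes instead.

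Gene lists, tests and the rule for named genes were fixed before the data were examined. The 37 lists held 698 genes (678 in the table, 40 of them at 0 throughout): homeostatic microglia, disease-associated microglia, MHC class I presentation, MHC class II presentation, type I interferon response, interferon-gamma response, chemokines and cytokines, NF-kB targets and feedback, complement, proliferation, cholesterol synthesis, lipid efflux and storage, respiratory complex I, respiratory complexes II to V, mitochondrially encoded, glycolysis, integrated stress response, AMPK and mTOR components, lysosome and autophagy, oxidative stress, H3K27 methylation enzymes, X-inactivation escape genes, ribosomal proteins, and markers of neurons, oligodendrocytes, oligodendrocyte precursors, astrocytes, endothelial cells, mural cells and fibroblasts, Schwann cells, T cells, B and plasma cells, neutrophils, monocyte-derived cells, border macrophages, dendritic cells and erythroid cells. Lists were tested with camera (limma 3.58.1, correlation 0.01, log2 CPM with prior count 1), adjusted over the 37 lists of a comparison, beside camera with an estimated correlation and fry. Members were counted at the adjusted p over all genes and adjusted over the list alone. Marker scores, the mean log2 CPM of the marker lists of other cells per library, were compared in exact two-sided permutation tests over 924 assignments, adjusted over 42 tests. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for these and for figures.

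Named genes were, per comparison, the 10 largest rises and the 10 largest falls among genes past the threshold with a mean of at least 5 CPM over the 18 libraries and no overlap between the groups, skipping unnamed and predicted genes, the 3 members of each list with the smallest p (2 for lists of other cells), and Kdm6a, Kdm6b, Xist, Uty, Ddx3y, Tmem119, P2ry12 and Rpl22. Other genes named are said to have been chosen after their values were seen. A fold against a group at 0 was bounded with a floor of 3 counts per library.

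The fit was tested on simulated data with known changes. Each gene had 1 mean over all 18 libraries and the spread of these libraries, and genes were drawn singly. Changes were put into 67 (1.5-fold), 67 (2-fold) and 66 (4-fold) genes with higher counts. In the real data many more genes were called and genes moved together, so the shares below may not hold there. For control EAE against healthy it recovered 35.8% of 1.5-fold, 76.1% of 2-fold and 95.5% of 4-fold changes with 3.5% false calls. For metformin against control EAE it recovered 31.3, 77.6 and 95.5% with 2.86% false calls, and for metformin against healthy 43.3, 77.6 and 97% with 2.68%. A cholesterol synthesis list shifted 1.5-fold was called, and 2 of 37 lists were called in that simulation.

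The share of EAE changes reversed under metformin was set against simulated libraries and against splits of the control EAE libraries into 3 and 3 over all 20 assignments, since both comparisons use control EAE. Calls were also counted in 100 splits of the 12 libraries of each comparison. Alternatives were RLE, upper-quartile scaling and DESeq2 1.42.0, limma-voom, no filter, a filter at 5 CPM in 6 libraries, a fit of 2 groups, the numbering run and the marker score as covariates, the fit without the robust setting, thresholds of 0.01 and 2-fold, medians for marker scores, and each library left out in turn. Chosen after seeing the data were library totals alone, the numbering runs alone, leaving out control EAE replicate 10 and metformin replicate 22 together, lists and reversal share without metformin replicate 22, and marker scores with each library left out. The numbering run follows replicate numbers 1 to 8, 9 to 16 and 17 to 24, and the labels do not say that a run is a batch. Splicing and transcript isoforms were left out, since the table holds 1 count per gene.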

Results

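RNA of spinal cord microglia, the resident macrophages of the central nervous system, was sequenced in 18 libraries from female wild-type mice. The mice carried Tmem119-Cre and RiboTag, a Cre-dependent epitope tag on the ribosomal protein Rpl22 that allows ribosome-bound RNA of the tagged cells to be pulled down. The 3 groups of 6 libraries came from control-treated healthy mice, from control-treated mice with experimental autoimmune encephalomyelitis (EAE, an immune-mediated model of multiple sclerosis) and from EAE mice given metformin. Metformin is an antidiabetic drug that inhibits respiratory complex I and activates the kinase AMPK. The libraries held 46.2 to 58.3 M gene counts (M, mega; mean 51.4 ± 3.52 M, SD, n = 18). The Y-linked genes Uty and Ddx3y had 0 counts in every library, as did some genes that all cells use, so these 0 values alone do not show the sex of the mice. The labels do not say that replicates are separate animals, so p-values measure only the spread between these samples.

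The comparison of control EAE with healthy cord asks how the disease changes microglial RNA. Homeostatic microglial genes fell in EAE, and genes of activated microglia, interferon responses, lipid handling and the nuclear-encoded respiratory chain rose. Markers of monocyte-derived cells, T cells and border macrophages rose as well, and the labels describe no pull-down. These data therefore do not separate changes inside microglia from RNA of other cells for these lists. P2ry12, the ADP receptor of resting microglia (ENSMUSG00000036353, chromosome 3, 59216272 to 59262871 in mm10), was at 81.5 ± 30.5 CPM (counts scaled to a common library size that was adjusted by TMM factors) in EAE and 636 ± 164 CPM in healthy cord (SD, n = 6 per group). Apoe, a lipid carrier (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188), was at 166000 ± 30300 CPM in EAE and 3220 ± 1280 CPM in healthy cord. It alone took 11.3 to 16.5% of the unadjusted counts of each control EAE library, whose TMM factors of 0.80 to 0.96 raise its CPM. Cd74, the invariant chain of MHC class II molecules (ENSMUSG00000024610, chromosome 18, 60803848 to 60812652), was at 6440 ± 2100 CPM and 65.1 ± 9.49 CPM.

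Of 19 homeostatic genes tested, 18 fell and 1 did not pass the test. Examples, given here and for all later genes as log2 change ± SE, were P2ry12 (-2.96 ± 0.35, adjusted p = 2e-06), the microglial marker Tmem119 (-1.74 ± 0.19, adjusted p = 3.71e-07), the transcription factor Sall1 (-2.28 ± 0.20), the matrix protein Sparc (-2.04 ± 0.18) and the fractalkine receptor Cx3cr1 (-2.08 ± 0.20). All 24 disease-associated microglial genes tested rose, among them Apoe (5.69 ± 0.49, adjusted p = 1.07e-07), the tetraspanin Cd63 (3.15 ± 0.26) and the cathepsin Ctsz (1.76 ± 0.17). The list test (camera) called the first list lower (adjusted p = 3.92e-08) and the second higher (adjusted p = 9.9e-11). With an estimated correlation each had an adjusted p = 0.304.

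**Figure D1:**
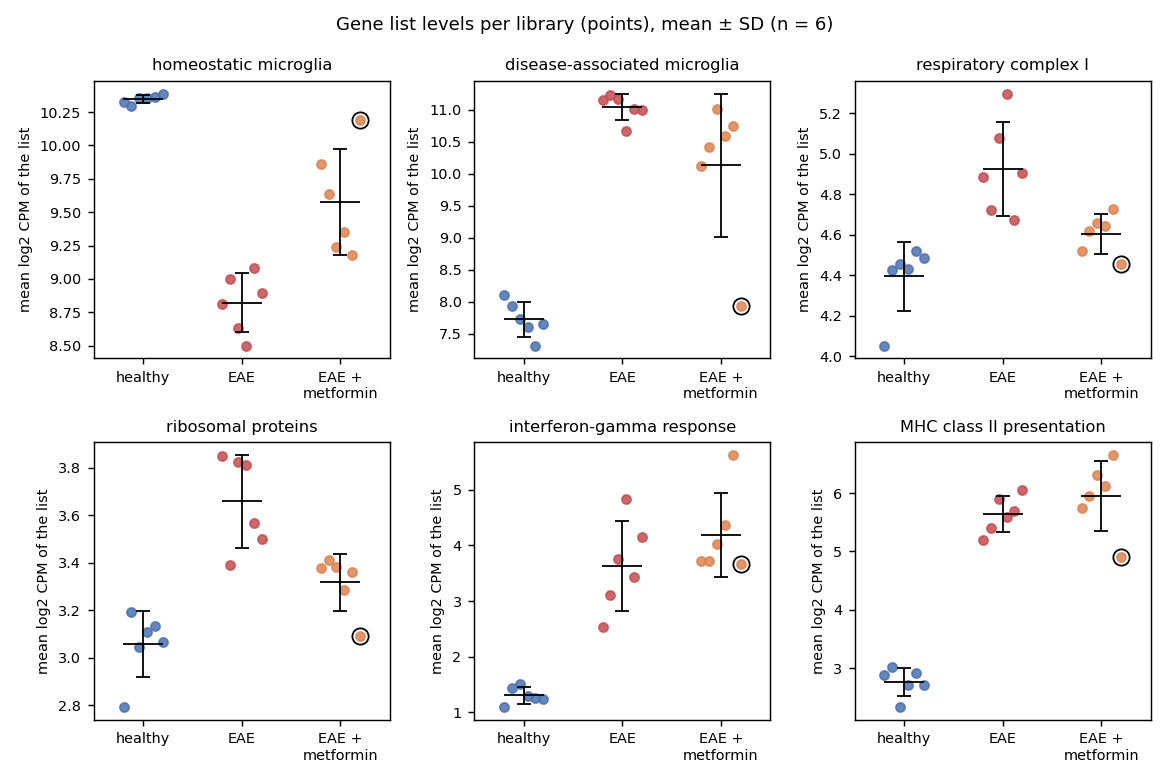
Mean log2 CPM of 6 gene lists per library (y axis) in the 3 groups of 6 libraries, with bars for the mean and SD of each group and a ring around metformin EAE replicate 22. All 24 disease-associated genes tested rose in EAE and 18 of 19 homeostatic genes fell, and replicate 22 lies nearest the healthy libraries in several panels.

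MHC class I presentation and both interferon lists rose as groups, and MHC class II presentation was not called. The class II list was tested without its H2 genes, such as H2-Aa and H2-Ab1, which were at 0 in every library. All 7 MHC class I presentation genes tested rose, among them the class I gene H2-Q4 (2.48 ± 0.19), which has near-identical relatives, and the class I transactivator Nlrc5 (3.17 ± 0.24). Of 5 MHC class II presentation genes, 3 rose, including Cd74 (6.63 ± 0.51, adjusted p = 7.85e-08), the co-stimulator Cd80 fell (-1.32 ± 0.17) and 1 did not pass. Of 26 type I interferon response genes 23 rose, including Oasl2 (2.72 ± 0.27) and Usp18 (2.39 ± 0.25). Of 15 interferon-gamma response genes 13 rose, including the chemokine Cxcl9 (6.80 ± 0.65). In neither interferon list did a gene fall. Camera gave adjusted p = 0.000198 for class I, 0.184 for class II, 1.77e-07 for type I interferon and 0.000331 for interferon-gamma. The adjusted p was 0.304 with an estimated correlation for all of these but class II (0.329).

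Inflammatory mediators followed. Of 22 chemokine and cytokine genes 18 rose and 2 fell (adjusted p = 0.000313), with the interleukin-18 inhibitor Il18bp at 6.45 ± 0.68 and the cytokine Osm at 1.29 ± 0.15. Of 16 NF-kB targets 12 rose and 3 fell (adjusted p = 0.0229), with the survival gene Bcl2a1b at 1.39 ± 0.12 and Tnfaip2 at 2.30 ± 0.25. Of 12 complement genes 9 rose and 2 fell (adjusted p = 0.0097), with C3 at 4.48 ± 0.49 and the complement receptor subunit Itgam at -1.17 ± 0.12. Each of these lists had an adjusted p = 0.304 with an estimated correlation. Of 29 proliferation genes 17 rose and 0 fell (adjusted p = 0.0323), with the replication clamp Pcna at 0.78 ± 0.12. Its adjusted p was 0.643 with an estimated correlation.

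Lipid and lysosomal genes rose in EAE. Of 23 lipid efflux and storage genes 16 rose and 2 fell (adjusted p = 5.11e-05), with the lipid droplet protein Plin3 at 2.25 ± 0.19 and the lysosomal cholesterol carrier Npc2 at 1.44 ± 0.14. Of 26 lysosome and autophagy genes 22 rose and 1 fell (adjusted p = 1.99e-06), including the cathepsins Ctsa (1.74 ± 0.17) and Ctsk (2.83 ± 0.31). Of 20 oxidative stress genes 14 rose and 1 fell (adjusted p = 0.000764), with the NADPH oxidase subunits Cybb at 4.81 ± 0.47 and Cyba at 1.76 ± 0.17. These 3 lists had an adjusted p = 0.304 with an estimated correlation. Cholesterol synthesis genes went both ways, 6 up and 9 down of 21 (adjusted p = 0.304), with squalene epoxidase Sqle at -1.53 ± 0.17 and phosphomevalonate kinase Pmvk at 0.92 ± 0.13.

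Nuclear genes of the respiratory chain and mitochondrially encoded genes went opposite ways. Of 34 complex I genes 30 rose and 1 fell (adjusted p = 3.88e-07). Of 35 genes of complexes II to V 30 rose and 1 fell (adjusted p = 6.12e-08). Random gene lists matched on length and expression also rose, by a median of 0.322 and 0.312 against 0.648 and 0.852 for these 2 lists, which lay above the central 95% of the random lists (upper ends 0.548 and 0.545). Ndufa1 was at 1.43 ± 0.15, Ndufa13 at 0.95 ± 0.13, Cox4i1 at 1.10 ± 0.12 and Sdhb at 0.90 ± 0.10. All 7 mitochondrially encoded genes tested fell (adjusted p = 0.0182), with mt-Co1 at -1.43 ± 0.31 and mt-Cytb at -1.85 ± 0.43. Mitochondrial counts were 0.236 and 0.238% of the total in healthy replicates 3 and 4 and 0.643 to 0.714% in the other 4 healthy libraries, against 0.077 to 0.177% in control EAE. Adjusted p was 0.304, 0.304 and 0.427 with an estimated correlation. Neuron and oligodendrocyte markers fell beside the mitochondrially encoded genes, and astrocyte markers went both ways. With the score of those markers as a covariate the median of the mitochondrially encoded list turned from -1.44 to 0.41. That score was -1.63 to -0.08 in control EAE and 0.58 to 1.49 in healthy libraries, without overlap. Values with this covariate in EAE against healthy are therefore extrapolated and cannot separate disease from RNA of other cells. Of 19 glycolysis genes 13 rose and 5 fell (adjusted p = 0.128), with pyruvate kinase Pkm at 1.44 ± 0.20 and hexokinase Hk1 at -0.76 ± 0.10. Of 24 integrated stress response genes 17 rose and 3 fell (adjusted p = 0.00263, and adjusted p = 0.304 with an estimated correlation). Among them were the serine synthesis enzyme Psat1 at 2.11 ± 0.18, the transcription factor Atf5 at 1.38 ± 0.12, and a fall of the amino acid transporter Slc7a5. AMPK and mTOR components were split, 4 up and 7 down of 17 (adjusted p = 0.291), with Eif4ebp1 at 0.84 ± 0.10 and Rptor at -1.28 ± 0.17.

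Of 72 ribosomal protein genes 53 rose and 1 fell (adjusted p = 1.84e-07, and adjusted p = 0.304 with an estimated correlation). The median was 0.56, against 0.207 (upper end of the central 95% 0.388) in random lists matched on length and expression. Rpl41, of a family with near-identical copies, was at 1.30 ± 0.14. Rpl22, the protein that carries the tag, rose by 0.61 ± 0.08 (adjusted p = 4.22e-06), a call that was lost when library totals alone set the scale. The series title concerns Kdm6a, an X-linked H3K27 demethylase. All mice here were labelled wild type. Kdm6a (ENSMUSG00000037369, chromosome X, 18162575 to 18279936) fell by 0.83 ± 0.23 on the log2 scale (adjusted p = 0.00442), from 7.82 ± 2.18 to 4.39 ± 1.57 CPM, and its relative Kdm6b fell by 1.58 ± 0.16. With the marker score as a covariate the Kdm6a change was 0.04. Xist, the RNA of the inactive X chromosome, fell (-2.07 ± 0.56, adjusted p = 0.00401), and its change was 0.16 with that covariate. Since the marker score did not overlap between control EAE and healthy libraries, these values do not show that RNA from other cells caused the falls. Of 6 H3K27 methylation enzymes 1 rose and 2 fell (adjusted p = 0.304). Of 7 genes that escape X inactivation 3 rose and 3 fell (adjusted p = 0.759).

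Markers of other cells moved with the disease. All 15 neuron markers fell (adjusted p = 2.21e-05), with the vesicular GABA transporter Slc32a1 at -1.59 ± 0.20 and the enolase Eno2 at -1.16 ± 0.16. Similarly, 8 of 10 oligodendrocyte markers fell (adjusted p = 0.00788), with Cnp at -0.58 ± 0.09 and Mobp at -0.75 ± 0.12. Of 10 monocyte-derived cell markers 8 rose (adjusted p = 0.0023). Of 6 T cell markers 5 rose and 1 fell (adjusted p = 0.0341), with Cd3e at 6.53 ± 1.10. In healthy cord only replicate 4 stood above the shared lowest level of Cd3e. Of 5 border macrophage markers 4 rose (adjusted p = 0.0424), with Ms4a7 at 7.86 ± 0.81. These 5 lists had an adjusted p = 0.304 with an estimated correlation. Of 9 mural cell and fibroblast markers 6 rose and 1 fell (adjusted p = 0.0238, and adjusted p = 0.427 with an estimated correlation), with Col3a1 at 5.06 ± 0.62 and Dcn at 3.22 ± 0.44. Camera did not call astrocyte markers (2 up and 5 down of 10, adjusted p = 0.161), oligodendrocyte precursor markers (2 up and 4 down of 8, 0.393) or endothelial markers (4 up and 3 down of 10, 0.943). Nor did it call Schwann cell markers (2 up and 0 down of 4, 0.396), B and plasma cell markers (2 up and 2 down of 4, 0.897), neutrophil markers (both tested rose, 0.0502, and 0.0139 without metformin replicate 22), dendritic cell markers (1 up and 1 down of 5, 0.985) or erythroid markers (0 up and 1 down of 2, 0.511). Marker scores, the mean marker log2 CPM per library, were compared in exact two-sided permutation tests. Neuron (-1.29), oligodendrocyte (-0.66) and astrocyte (-0.43) scores were lower in EAE and mural cell and fibroblast (2.33), T cell (3.24), neutrophil (6.13), monocyte-derived (3.41) and border macrophage (3.18) scores higher. Each had an exact permutation adjusted p = 0.00825 and no overlap between 6 and 6 libraries. The neutrophil score, over 2 markers, had the same lowest value (-5.69) in healthy replicates 19 and 20, as at 0 counts, so its size depends on a floor. With overlap, the B and plasma cell score (2.33, adjusted p = 0.0152) and the Schwann cell score (1.39, adjusted p = 0.0496) were also higher. The Schwann cell call was lost when any 1 of 10 libraries was left out (largest adjusted p = 0.108, without control EAE replicate 10), and the erythroid score (-1.39, adjusted p = 0.0569) passed only without control EAE replicate 10 (0.0227).

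Some directions rested on 5 genes or fewer, named here after their values were seen where the rule for named genes did not choose them. Beside those already given, falls were in Ccl9 and Il6 among chemokines and cytokines, Rel, Nfkbie and Nfkb1 among NF-kB genes, and Fasn and Scd1 among lipid genes. Other falls were in Ndufab1 and Atp5g1 in the respiratory chain, Hk2, Aldoc, Pfkm and Gapdh in glycolysis, Vldlr and Cebpg in the stress response, Man2b1 in the lysosome, Gclc in oxidative stress and Rpl5 among ribosomal proteins. Cd40 and Ciita rose in MHC class II presentation, Rps6kb1, Rheb and Prkag1 among AMPK and mTOR components, and Suz12 among H3K27 methylation enzymes. Also up were Ddx3x, Pbdc1 and Utp14a among escape genes, and Kdm5c and Usp9x fell. Among markers, Pdgfra, Cspg4, Gfap, Aldh1l1, Flt1, Itm2a, Cdh5, Emcn, Prx, Cd3g, Cd4, Lat, Il2rb, Jchain, Igkc, Mmp8, S100a8, Mrc1, Folr2, F13a1 and Cd24a rose. Markers that fell were Sox10, Olig1, Olig2, C1ql1, Slc1a2, Slc1a3, Slc6a11, Gja1, Fgfr3, Tek, Slco1a4, Rgs5, Thy1, Cd79b, Ighm, Flt3 and Hbb-bs. Leaving out 1 library ended some of these calls. In brackets are the number of libraries with that effect and the highest adjusted p. In EAE these were Cdh5 (9, 0.106 without control EAE replicate 9), Cebpg (7, 0.0791 without control EAE replicate 1), Fasn (13, 0.102 without control EAE replicate 18), Man2b1 (1, 0.0532 without healthy replicate 3), Ndufab1 (8, 0.0833 without control EAE replicate 18) and Rheb (4, 0.082 without healthy replicate 3). So were Slco1a4 (1, 0.0952 without healthy replicate 4 at -0.94), Suz12 (3, 0.104 without control EAE replicate 10 at 0.33), Tek (4, 0.129 without healthy replicate 4 at -1.03), Usp9x (7, 0.0749 without control EAE replicate 1) and Vldlr (3, 0.0543 without healthy replicate 20). Without control EAE replicate 10 Fasn was at -0.22, without healthy replicate 19 Cd3g was at 7.71 and without healthy replicate 4 Lat was at 7.06. For Cd3g and Lat the remaining healthy libraries then had equal log2 CPM, as at 0 counts, so both sizes depend on a floor. With library totals alone Gfap (-0.10), Prkag1 (-0.17) and Rheb (-0.22) turned lower and Cd24a, Cdh5, Ddx3x, Suz12 and Utp14a lost their calls. With the marker score as a covariate Cebpg (0.04), Ndufab1 (0.28), Thy1 (0.04), Usp9x (0.29) and Vldlr (0.43) turned higher.

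The largest rises among abundant genes without overlap between the groups were in the acute-phase gene Saa3 (10.75 ± 1.26), the chemokine Ccl8 (9.92 ± 1.21), the apolipoprotein Apoc4 (8.83 ± 0.95), the fatty acid carrier Fabp4 (8.30 ± 0.88), the proton pump subunit Atp6v0d2 (8.26 ± 0.85), heparanase Hpse (8.26 ± 0.83), the glycoprotein Gpnmb (8.25 ± 0.97), the lectin receptor Clec4d (8.11 ± 0.87) and the phospholipase Pla2g2d (7.96 ± 0.96). Serpina3f, one of several near-identical serpins, had 0 counts in healthy cord and was at least 120-fold higher in EAE at a floor of 3 counts per library. The largest falls were in the platelet glycoprotein Gp9 (-6.14 ± 0.74), the uroplakin Upk1b (-5.54 ± 0.53), the potassium channel Kcnk12 (-4.75 ± 0.54), Trp53bp1 (-4.56 ± 0.56), Bcar1 (-4.22 ± 0.48), Lrba (-3.98 ± 0.41), the integrin Itga9 (-3.95 ± 0.50), Tubgcp4 (-3.95 ± 0.47), Pecam1 (-3.88 ± 0.37) and Klhdc8b (-3.85 ± 0.39). Trp53bp1 (ENSMUSG00000043909, chromosome 2, 121193281 to 121271407) and Tubgcp4 (ENSMUSG00000027263, chromosome 2, 121170654 to 121198770) overlap, so counts of one may include reads of the other.

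Of 16740 genes tested, 5314 rose and 5138 fell (edgeR quasi-likelihood F test, adjusted p under 0.05), and 2024 rose and 2112 fell by at least 2-fold. In 6599 genes the 6 EAE and 6 healthy libraries did not overlap (chance share 0.216%). Camera called 19 of 37 lists higher and 4 lower, 0 with an estimated correlation (0 at an unadjusted p under 0.05), and fry called 32. Counts per list were the same adjusted over the list alone for 32 of the 37. The others were chemokines and cytokines (3 fell), complement (10 rose), complexes II to V (31 rose), integrated stress response (4 fell) and endothelial markers (4 fell). When library totals alone set the scale, the median of all genes moved to -0.42, calls were 2604 up and 8649 down. Complex I then counted 12 up and 4 down, and ribosomal proteins 20 up and 8 down. With the marker score as a covariate 4534 genes were called.

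The comparison of metformin-treated with control-treated EAE asks what the drug changes in diseased cord. Most homeostatic genes rose with metformin, and most nuclear-encoded respiratory chain genes and a minority of disease-associated genes (8 of 24) and ribosomal protein genes (30 of 72) fell. Camera called each of these lists, and 0 lists were called with an estimated correlation (adjusted p = 0.542 to 0.7 for these). RNA of other cells was not separated from changes inside microglia in these lists. MHC class I, MHC class II and interferon lists were not called, and without metformin replicate 22 camera called MHC class II (adjusted p = 0.0496) and the interferon-gamma list (adjusted p = 0.0253) higher. P2ry12 was at 312 ± 199 CPM with metformin and 81.5 ± 30.5 CPM in control EAE (SD, n = 6 per group), Tmem119 (ENSMUSG00000054675, chromosome 5, 113793729 to 113800516) at 605 ± 219 and 318 ± 49.8 CPM, and Apoe at 72900 ± 34200 and 166000 ± 30300 CPM. In metformin replicate 22 these genes were at 696, 970 and 7080 CPM, against 171 to 361, 373 to 697 and 65100 to 97200 CPM in the other 5 metformin libraries.

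**Figure D2:**
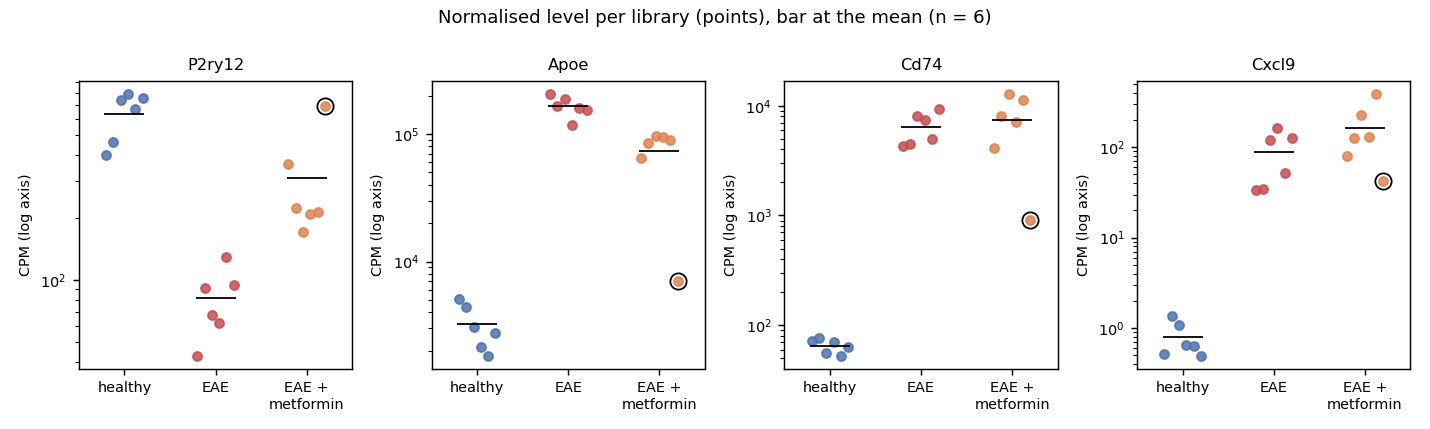
CPM of P2ry12, Apoe, Cd74 and Cxcl9 in each library (log axis), with a bar at the mean of each group of 6. P2ry12 and Apoe lie between control EAE and healthy cord in the metformin group, and the mean of Cxcl9 was 165 CPM with metformin and 88.3 CPM in control EAE, a difference that did not pass the test.

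Of 19 homeostatic genes 13 rose with metformin and 0 fell (16 rose and 1 fell adjusted over the list alone), with P2ry12 at 1.94 ± 0.34 (adjusted p = 0.00185), Tmem119 at 0.93 ± 0.18 (adjusted p = 0.0025), Sall1 at 1.39 ± 0.19, Cx3cr1 at 1.36 ± 0.20 and the lysophospholipid receptor Gpr34 at 1.04 ± 0.18. Camera called the list higher (adjusted p = 1.2e-07, and adjusted p = 0.542 with an estimated correlation). Of 24 disease-associated genes 8 fell and 0 rose (9 fell adjusted over the list alone), with the adaptor Tyrobp at -0.63 ± 0.13, Cd63 at -0.96 ± 0.24 and Ctsz at -0.62 ± 0.16 (camera adjusted p = 3.54e-06, and adjusted p = 0.7 with an estimated correlation). The mean log2 CPM of the disease-associated list was 11.04 in control EAE, 7.94 in metformin replicate 22 and 10.57 in the other 5 metformin libraries, and without replicate 22 again 8 genes fell (camera adjusted p = 3.71e-06). Apoe, like Cd74 and Cxcl9 in the plot of gene levels, was chosen for this comparison after its values were seen and was at -1.19 ± 0.40 (adjusted p = 0.0388). The Apoe call was lost without control EAE replicate 1 (0.0729), 2 (0.0562), 9 (0.0682) or 18 (0.0535) or metformin replicate 5 (0.0722) or 6 (0.0568).

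Of 7 MHC class I genes 0 passed the test at the edgeR adjusted p (0 adjusted over the list alone), and camera gave adjusted p = 0.652. Of 5 class II genes the co-stimulators Cd86 (0.43 ± 0.08) and Cd80 (0.65 ± 0.17) rose (3 adjusted over the list alone, camera adjusted p = 0.229, and 0.0496 without metformin replicate 22). Of 26 type I interferon genes Parp14 rose (0.34 ± 0.10) and Bst2 fell (-0.67 ± 0.20), the latter lost with library totals alone (camera adjusted p = 0.652). Of 15 interferon-gamma genes Icam1 (0.35 ± 0.12, adjusted p = 0.0356) and Tgtp1 (adjusted p = 0.0374) rose, 0 adjusted over the list alone, and camera gave adjusted p = 0.102. Without metformin replicate 22 camera called the interferon-gamma list higher (adjusted p = 0.0253). With all libraries and an estimated correlation, camera gave that list an adjusted p = 0.701. Tgtp1 was at 1.17 without metformin replicate 21 (adjusted p = 0.181) and also lost its call without control EAE replicate 1 (0.0689), 9 (0.0794) or 17 (0.0631) or metformin replicate 22 (0.0524). Icam1 lost its call without control EAE replicate 2 (0.0635) or 9 (0.0513) or metformin replicate 5 (0.0586), 6 (0.0611), 13 (0.0515), 14 (0.0614) or 21 (0.0622). Of 22 chemokine and cytokine genes 1 rose and 2 fell (0 adjusted over the list alone, camera adjusted p = 0.565). Of 29 proliferation genes 0 passed (camera adjusted p = 0.105). Of 12 complement genes 1 rose, Itgam (0.73 ± 0.12), and 1 fell (camera adjusted p = 0.65). Of 16 NF-kB genes 3 rose, including the inhibitor Nfkbie (0.67 ± 0.11) and Birc3 (0.57 ± 0.10), and the inhibitor Nfkbia fell (-0.59 ± 0.14, lost with library totals alone), with camera adjusted p = 0.419.

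Nuclear-encoded respiratory chain genes and part of the ribosomal protein genes fell with metformin. Of 34 complex I genes 25 fell (31 adjusted over the list alone) and 0 rose, with Ndufa2 at -0.79 ± 0.15, Ndufa13 at -0.65 ± 0.12 and Ndufb10 at -0.46 ± 0.08, the last lost with library totals alone. Of 35 genes of complexes II to V 25 fell (27 adjusted over the list alone) and 0 rose, with Cox4i1 at -0.71 ± 0.12, Cox6b1 at -0.71 ± 0.13 and Cox7a2 at -0.69 ± 0.13. Of 72 ribosomal protein genes 30 fell (38 adjusted over the list alone) and 0 rose, with Rplp2 at -0.74 ± 0.13 and Rpl22 at -0.40 ± 0.08 (adjusted p = 0.00303, lost with library totals alone). Camera gave adjusted p = 2.22e-11, 5.84e-11 and 1.59e-10 for these lists, each with an adjusted p = 0.542 with an estimated correlation. The 3 medians kept their sign with library totals alone, under which 7, 11 and 9 genes fell and 0, 1 and 0 rose. Of 24 integrated stress response genes 9 fell and 1 rose (adjusted p = 0.00119, and adjusted p = 0.542 with an estimated correlation), with Atf5 at -0.81 ± 0.12, Atf4 at -0.47 ± 0.09 and Psat1 at -0.84 ± 0.18. Of 19 glycolysis genes the hexokinase Hk2 rose (0.52 ± 0.10, camera adjusted p = 0.958), and of 17 AMPK and mTOR components 5 rose and 2 fell (camera adjusted p = 0.615).

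Mitochondrially encoded genes went the other way, with 5 of 7 rising (7 adjusted over the list alone), among them mt-Co1 (1.07 ± 0.30, adjusted p = 0.017) and mt-Nd5 (1.28 ± 0.38, adjusted p = 0.0218), and camera called the list higher (adjusted p = 0.00876, and adjusted p = 0.7 with an estimated correlation). Without metformin replicate 22 only 1 of the 7 rose, and mt-Nd5 was at 0.82 (adjusted p = 0.0638). Some neuron markers rose beside them, 4 of 15 (5 adjusted over the list alone, camera adjusted p = 0.00876, and adjusted p = 0.7 with an estimated correlation), with the neurofilament Nefl at 0.71 ± 0.17 and Snhg11 at 1.73 ± 0.43, which was at 1.13 without metformin replicate 22. The neuron marker score did not pass (0.50, exact permutation adjusted p = 0.0838, and 0.24 with medians of markers). It was 4.90 in metformin replicate 22, 3.34 to 3.86 in the other 5 metformin libraries and 2.94 to 3.88 in control EAE, so the difference was 0.30 without replicate 22 (adjusted p = 0.162), and 3 markers then rose. It passed without control EAE replicate 10 (0.0287) or metformin replicate 13 (0.0382). Mitochondrial counts were 0.345 ± 0.268% of the total with metformin, 0.140 ± 0.038% in control EAE and 0.533 ± 0.231% in healthy cord (SD, n = 6 each), and 0.884% in metformin replicate 22. Healthy replicates 3 and 4, the only healthy libraries with numbers from 1 to 8, were at 0.236 and 0.238%, within the 0.184 to 0.305% of the other 5 metformin libraries, and the other 4 healthy libraries at 0.643 to 0.714%. These percentages miss mt-Co2, mt-Co3, mt-Atp6 and mt-Atp8, which were at 0 in every library.

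Of 21 cholesterol synthesis genes 9 rose and 3 fell (12 and 4 adjusted over the list alone), with Sqle at 1.02 ± 0.16 and the sterol carrier Stard4 at 0.95 ± 0.14. Camera called the list higher (adjusted p = 0.00876, and adjusted p = 0.542 with an estimated correlation). Of 23 lipid efflux and storage genes 9 fell and 1 rose (10 and 2 adjusted over the list alone, adjusted p = 0.00876, and adjusted p = 0.7 with an estimated correlation), with Npc2 at -0.62 ± 0.14 and the desaturase Scd1 at 0.66 ± 0.14. Of 26 lysosome and autophagy genes 7 fell (adjusted p = 0.00231, and adjusted p = 0.7 with an estimated correlation), with Ctsk at -1.42 ± 0.29 and Hexa at -0.48 ± 0.12. Of 20 oxidative stress genes 8 fell and 1 rose (11 and 1 adjusted over the list alone, adjusted p = 0.00876, and adjusted p = 0.679 with an estimated correlation), with Cyba at -0.73 ± 0.16 and the glutathione synthesis enzyme Gclc at 0.41 ± 0.10. Metformin replicate 22 stood apart in the lipid, lysosome and oxidative stress lists, with mean log2 CPM of 5.17, 7.01 and 5.82. The other metformin libraries had means of 6.83, 8.01 and 6.52, and control EAE 7.22, 8.20 and 6.69.

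Kdm6a rose with metformin (0.65 ± 0.23, adjusted p = 0.0468) to 6.92 ± 1.01 CPM, and Kdm6b rose (0.49 ± 0.16, adjusted p = 0.0295), the 2 members of the H3K27 methylation enzymes (6 tested, camera adjusted p = 0.435) that passed. The Kdm6a call was lost without control EAE replicate 1 (0.0863), 2 (0.0812), 9 (0.0894) or 18 (0.0698), healthy replicate 3 (0.0536), 11 (0.0567), 12 (0.0555) or 20 (0.055), or metformin replicate 5 (0.0603), 6 (0.0755), 13 (0.0556), 14 (0.0817) or 22 (0.0908). The Kdm6b call was lost without control EAE replicate 9 (0.0711) or metformin replicate 22 (0.30, adjusted p = 0.0825). Xist rose (2.12 ± 0.56, adjusted p = 0.0124) to 16.5 ± 13.2 CPM from 3.80 ± 1.76 CPM, with 42.1 CPM in metformin replicate 22 and 6.93 to 18.9 CPM in the other 5.

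Among other cells, camera called only neuron markers. Of 4 Schwann cell markers 2 fell, among them the periaxin gene Prx (-2.11 ± 0.47) (camera adjusted p = 0.063, and 0.0268 without metformin replicate 22). With all libraries and an estimated correlation, camera gave the Schwann cell list an adjusted p = 0.542. Plac8 fell (-1.62 ± 0.39) among 10 monocyte-derived cell markers (camera adjusted p = 0.16). Further, 4 of 10 astrocyte markers rose and 1 fell (0.569), with the glutamate transporter Slc1a2 at 0.90 ± 0.23 and at 0.56 without metformin replicate 22. Of 5 dendritic cell markers Flt3 rose (1.53 ± 0.33) and Cd24a fell (-0.59 ± 0.15, lost with library totals alone; 0.565). In the exact two-sided permutation tests the dendritic cell score was higher with metformin (0.45, adjusted p = 0.00825, no overlap between 6 and 6 libraries, but adjusted p = 0.0506 with medians of markers). The Schwann cell (-1.76, adjusted p = 0.0284), border macrophage (-0.79, adjusted p = 0.0336) and neutrophil (-1.86, adjusted p = 0.0496) scores were lower. The border macrophage call was lost when any 1 of 8 libraries was left out (largest adjusted p = 0.0712, without control EAE replicate 9), and with medians of markers the difference was 0.01. The neutrophil call, over 2 markers, was lost when any 1 of 10 libraries was left out (largest adjusted p = 0.138, without control EAE replicate 9), and the difference was -0.895 without metformin replicate 22 (adjusted p = 0.0837).

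Where 5 genes or fewer made up a direction, further members were the cytokine Il1a, up, and Cxcl14 and Osm, down, Nfkb1, up among NF-kB genes, and C1qa, down among complement genes. Others were Pmvk, Ebp and Mvk, down in cholesterol synthesis, mt-Nd1, mt-Nd2 and mt-Cytb, up among mitochondrially encoded genes, and Slc7a5, up in the stress response. AMPK and mTOR components were Rptor, Tsc1, Prkab1, Rictor and Prkaa1, up, and Eif4ebp1 and Prkag1, down. Markers were Nefh and Slc32a1, up among neuron markers, and Slc1a3, Slc6a11 and Fgfr3, up, and Gfap, down, among astrocyte markers. Those the rule for named genes did not choose were named after their values were seen. Calls that ended when 1 library was left out, written in the same way, were C1qa (14, 0.0983 without metformin replicate 5), Cxcl14 (4, 0.0821 without control EAE replicate 1), Ebp (8, 0.0938 without metformin replicate 6), Eif4ebp1 (8, 0.0847 without metformin replicate 6), Gfap (5, 0.0675 without metformin replicate 5), Il1a (7, 0.0681 without control EAE replicate 1) and Osm (6, 0.066 without control EAE replicate 1). Others were Prkab1 (7, 0.124 without metformin replicate 22), Rictor (6, 0.112 without metformin replicate 22), Rptor (2, 0.0566 without metformin replicate 22), Slc32a1 (4, 0.0713 without metformin replicate 22 at 0.31), Slc6a11 (4, 0.0886 without metformin replicate 22 at 0.27), Tsc1 (8, 0.0756 without control EAE replicate 9), mt-Cytb (6, 0.135 without metformin replicate 22 at 0.67), mt-Nd1 (4, 0.104 without metformin replicate 22 at 0.78) and mt-Nd2 (4, 0.0988 without metformin replicate 22). Without metformin replicate 22 Nefh was at 0.61 and Fgfr3 at 0.33. With library totals alone C1qa, Ebp, Eif4ebp1, Gfap, Mvk, Osm, Pmvk and Prkag1 lost their calls.

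The largest rises were in Gp9 (3.42 ± 0.69, adjusted p = 0.00325), Upk1b (2.79 ± 0.50), Trp53bp1 (2.61 ± 0.51), Tubgcp4 (2.25 ± 0.43), Bcar1 (adjusted p = 0.00318), Xist, the microRNA host gene Mir124a-1hg (2.07 ± 0.40), Itga9 (2.06 ± 0.47), P2ry12 and the lectin Siglech (1.86 ± 0.35). Itga9 was at 1.32 without metformin replicate 22. The largest falls were in Fabp4 (-2.81 ± 0.61, adjusted p = 0.00436), the NAD-consuming enzyme Cd38 (-2.76 ± 0.48), Apoc4 (-2.41 ± 0.66), Ctla2a (-2.12 ± 0.38), Wnt4 (-2.06 ± 0.44), Gpx3 (-2.03 ± 0.64), Mgp (-1.77 ± 0.53), Apod (-1.74 ± 0.30), Apoc2 (-1.64 ± 0.51) and Adam8 (-1.63 ± 0.52). Gpx3 lost its call without control EAE replicate 9 (0.0554) or metformin replicate 5 (0.0611) or 6 (0.0506). Apoc2 lost it without control EAE replicate 9 (0.0656) or metformin replicate 5 (0.0623) or 6 (0.056), and Adam8 lost it without control EAE replicate 1 (0.0548), 2 (0.0513) or 9 (0.0622) or metformin replicate 5 (0.0649) or 6 (0.0645). Apoc2, Apoc4 and Apoe are neighbours on chromosome 7.

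Of 16740 genes tested, 2087 rose and 2024 fell with metformin (edgeR), 403 and 176 of them by at least 2-fold, and 1732 genes showed no overlap between 6 and 6 libraries (chance share 0.216%). Camera called 4 lists higher and 8 lower of 37, 0 with an estimated correlation (0 at an unadjusted p under 0.05), and fry called 10. Counts were the same adjusted over the list alone for 19 lists. When library totals alone set the scale, the median of all genes moved to 0.23 and calls were 4712 up and 616 down. The count of calls was 2703 with only the 12 libraries of both groups in the fit and 2519 with the marker score as a covariate.

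Metformin and disease shared the control EAE libraries, so their changes were set against a simulation. Of the 10452 genes changed in EAE, 91.5% had the opposite sign under metformin, against 55.1% in simulated data in which metformin libraries were drawn as control EAE. With control EAE split so that each comparison used its own 3 libraries, the share was 87.2% (79.2 to 91.9% over the splits). With the controls shared, it was 85.4% without metformin replicate 22. The simulation drew each gene on its own, while real genes moved together (estimated correlation 0.524 for homeostatic and 0.767 for disease-associated genes). A shift by chance that many genes share could also change this share. Neither the simulation nor the splits measure that. Of 5314 genes higher in EAE 1853 fell with metformin, and of 5138 genes lower in EAE 1861 rose. The same direction was called in both for 19 genes up and 5 genes down.

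**Figure D3:**
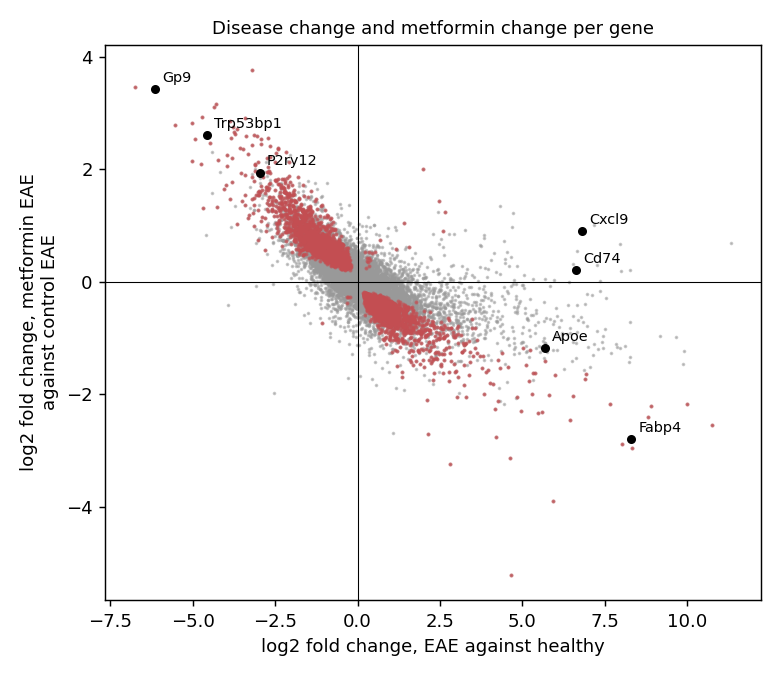
Log2 change in EAE against healthy cord (x axis) and under metformin against control EAE (y axis) for each gene tested, with genes called in both in red and 7 genes named. Of the genes higher in EAE 1853 fell with metformin and of those lower in EAE 1861 rose, and both axes share the control EAE libraries.

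The comparison of metformin-treated EAE with healthy cord asks what remained of the disease change. Interferon, antigen presentation and disease-associated genes stayed above healthy levels, and homeostatic genes below. Cxcl9 (ENSMUSG00000029417, chromosome 5, 92321347 to 92328079) was at 165 ± 124 CPM with metformin and 0.79 ± 0.35 CPM in healthy cord (7.70 ± 0.67, adjusted p = 1.02e-06, n = 6 per group). Cd74 was at 7380 ± 4410 and 65.1 ± 9.49 CPM (6.83 ± 0.51), and Apoe at 72900 ± 34200 and 3220 ± 1280 CPM (4.50 ± 0.46). P2ry12 was lower (-1.03 ± 0.33, adjusted p = 0.0214), a call lost without metformin replicate 13 (0.0508), 14 (0.0512) or 21 (0.0523), and Tmem119 was lower (-0.82 ± 0.18, adjusted p = 0.00179).

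All 7 MHC class I genes rose against healthy cord, with H2-Q4 at 2.64 ± 0.19, Nlrc5 at 3.45 ± 0.24 and B2m at 1.41 ± 0.14 (camera adjusted p = 2.23e-06). Further, 4 of 5 class II genes rose and 1 fell, with the class II transactivator Ciita at 5.93 ± 0.63 (camera adjusted p = 0.00392). Of 15 interferon-gamma genes 14 rose, with the guanylate-binding protein Gbp2 at 4.36 ± 0.52 (camera adjusted p = 3.63e-09). These 3 lists had an adjusted p = 0.19 with an estimated correlation. Of 26 type I interferon genes 24 rose, with Oasl2 at 2.62 ± 0.27 and Usp18 at 1.99 ± 0.25 (camera adjusted p = 8.49e-13). Of 24 disease-associated genes 22 rose, with the receptor kinase Axl at 3.26 ± 0.34 (camera adjusted p = 1.4e-12). Each had an adjusted p = 0.234 with an estimated correlation. Of 19 homeostatic genes 16 fell, with Sparc at -1.15 ± 0.18 and cystatin C, Cst3, at -1.10 ± 0.18 (camera adjusted p = 3.51e-07, and adjusted p = 0.235 with an estimated correlation). Of 22 chemokine and cytokine genes 16 rose and 1 fell (adjusted p = 3.61e-06, and adjusted p = 0.19 with an estimated correlation), with Il18bp at 5.62 ± 0.66 and Ccl5 at 5.29 ± 0.71.

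Fewer respiratory chain and ribosomal protein genes stood apart from healthy cord than in control EAE. Of 34 complex I genes 7 rose (adjusted p = 0.0273, and adjusted p = 0.65 with an estimated correlation), with Ndufa1 at 0.68 ± 0.15. Of 72 ribosomal protein genes 17 rose and 1 fell (10 rose and 1 fell adjusted over the list alone, adjusted p = 0.00688, and adjusted p = 0.568 with an estimated correlation), with Rpl39 at 1.91 ± 0.29. With library totals alone the medians of these 2 lists turned from 0.17 to -0.03 and from 0.18 to -0.03. Of 35 genes of complexes II to V 13 rose and 1 fell (adjusted p = 0.000622, and adjusted p = 0.449 with an estimated correlation), with Sdhd at 0.57 ± 0.10. Without metformin replicate 22 these 3 lists counted 11, 22 and 20 rises. Of 7 mitochondrially encoded genes 0 passed the test (camera adjusted p = 0.216), with mt-Co1 at -0.36 ± 0.30 (adjusted p = 0.361), and 5 fell without metformin replicate 22. Of 23 lipid efflux and storage genes 16 rose and 1 fell (adjusted p = 5.24e-06, and adjusted p = 0.259 with an estimated correlation), with the fatty acid carrier Cd36 at 5.08 ± 0.54 and Fabp5 at 4.01 ± 0.45. Kdm6a (-0.18 ± 0.23, adjusted p = 0.57), Xist (0.05 ± 0.53, adjusted p = 0.948) and Rpl22 (0.21 ± 0.08, adjusted p = 0.0541) did not pass the test, and Kdm6b fell (-1.08 ± 0.16).

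Of 15 neuron markers 9 fell (12 adjusted over the list alone, 14 without metformin replicate 22, adjusted p = 1.72e-05, and adjusted p = 0.328 with an estimated correlation), 8 of 10 oligodendrocyte markers fell (adjusted p = 0.000257, and adjusted p = 0.234 with an estimated correlation) and 7 of 10 monocyte-derived cell markers rose (adjusted p = 0.000442, and adjusted p = 0.234 with an estimated correlation). In the exact two-sided permutation tests the T cell (2.65) and border macrophage (2.39) scores were higher than in healthy cord (adjusted p = 0.00825 each, no overlap between 6 and 6 libraries). Monocyte-derived cell (2.56, adjusted p = 0.0195), B and plasma cell (1.995, 0.0242), mural cell and fibroblast (1.73, 0.0321) and neutrophil (4.27, 0.0336) scores were also higher, and oligodendrocyte (-0.56, 0.0195) and neuron (-0.78, 0.041) scores lower. The neutrophil score had the same lowest value (-5.69) in healthy replicates 19 and 20 and metformin replicate 22, as at 0 counts, so its size depends on a floor. The neuron call was lost when any 1 of 9 libraries was left out (largest adjusted p = 0.0736, without healthy replicate 19) and the mural cell and fibroblast call when any 1 of 7 was (0.059, without healthy replicate 20). The astrocyte score (-0.26, adjusted p = 0.0553) passed without metformin replicate 22 (0.00567) and with medians of markers (0.0273), and the dendritic cell score (0.40, 0.0655) without healthy replicate 3 (0.0152). The largest rises were in Serpina3f (at least 194-fold at the floor of 3 counts per library), Ccl8 (8.68 ± 1.20), the itaconate-producing enzyme Acod1 (8.62 ± 0.87), Saa3 (8.20 ± 1.18), Cxcl9, Hpse (7.53 ± 0.81), Atp6v0d2 (6.91 ± 0.82), the receptor Slamf7 (6.87 ± 0.68), the interferon-induced GTPase Iigp1 (6.87 ± 0.89) and Mir5107 (6.86 ± 0.56), which lies within Cd74 and may hold its reads. The largest falls were in the semaphorin Sema4b (-3.17 ± 0.22), Klhdc8b (-2.88 ± 0.37), Upk1b (-2.75 ± 0.45), Gp9 (-2.72 ± 0.60), Kcnk12 (-2.66 ± 0.47), Nrarp (-2.62 ± 0.25), Pecam1 (-2.42 ± 0.34), Gimap6 (-2.29 ± 0.25), Lrba (-2.26 ± 0.38) and Ctnnd2 (-2.23 ± 0.19).

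Other lists called higher were NF-kB targets (camera adjusted p = 2.67e-05, and adjusted p = 0.19 with an estimated correlation), complement (0.000537, 0.19), lysosome and autophagy (2.23e-06, 0.259) and oxidative stress (0.00372, 0.292). So were glycolysis (0.0168, 0.365), the integrated stress response (0.0481, 0.419), mural cell and fibroblast (0.0168, 0.419), T cell (0.0168, 0.235), border macrophage (0.0259, 0.19) and neutrophil markers (0.0357). The median of oxidative stress genes turned from 0.16 to -0.04 with library totals alone. Directions made up of 5 genes or fewer held Cd40 and Cd86, up, and Cd80, down, in MHC class II presentation, Il6, down among chemokines and cytokines, Rpl5, down among ribosomal proteins, Atp5g1, down in complexes II to V, and Scd1, down among lipid genes, named after their values were seen unless chosen by the rule. The Cd86 call was lost with library totals alone.

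Of 16740 genes tested, 3405 were higher and 2730 lower with metformin than in healthy cord (edgeR), 1217 and 467 by at least 2-fold, and 2167 showed no overlap between 6 and 6 libraries (chance share 0.216%). Camera called 21 lists higher and 3 lower, 0 with an estimated correlation (7 at an unadjusted p under 0.05), and fry called 26. Counts were the same adjusted over the list alone for 29 of the 37. When library totals alone set the scale, the median of all genes moved to -0.20 and calls were 1927 up and 4786 down; upper-quartile scaling gave 2838 up and 3497 down, and the marker score as a covariate 2230 calls.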

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

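The tests of metformin replicate 22, of RNA from other cells and of 1 milder disease state were chosen only after the results they concern were seen. The splits of libraries were written before. The test of gene length was written before it was run, but it was not part of the plan fixed before the data were examined.

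In 117 of 726 groups of 6 libraries, the gap between the highest or lowest library and its nearest neighbour, as a share of the range of the group, was above Dixon's limit for 6 values, which chance alone passes in about 1 of 20 groups (36.3 of 726). Of these values 70 fell on metformin replicate 22. The numbers that follow are that share. Metformin replicate 22 was lowest of its group in Adam8 0.639, Apoc2 0.661, Apoc4 0.673, Apoe 0.847, Atf5 0.742, Atp6v0d2 0.758, Axl 0.725, B2m 0.73, Bcl2a1b 0.752, C3 0.778, Cd3e 0.643, Cd63 0.68, Clec4d 0.849, Col3a1 0.749, Cox4i1 0.658, Cspg4 0.709, Ctsk 0.722, Cybb 0.705, Dcn 0.729, Ddx3x 0.817, Fabp4 0.673, Fabp5 0.721, Flt1 0.749, Gpnmb 0.678, Gpx3 0.81, Hpse 0.739, Icam1 0.698, Mgp 0.677, Mmp8 0.777, Ms4a7 0.842, Osm 0.656, Pbdc1 0.644, Pcna 0.637, Pla2g2d 0.738, Rpl39 0.891, Rpl41 0.693, S100a8 0.723, Sdhb 0.715, Slamf7 0.798 and Usp18 0.671. It was highest in Ctnnd2 0.65, Fgfr3 0.671, Flt3 0.78, Itgam 0.825, Kdm6b 0.644, Mir124a-1hg 0.686, Mobp 0.743, Nefh 0.693, Nefl 0.704, Olig1 0.671, Pfkm 0.694, Sema4b 0.701, Slc1a2 0.774, Slc32a1 0.63, Sox10 0.831, Vldlr 0.786, mt-Co1 0.683, mt-Cytb 0.676 and mt-Nd1 0.646. Among mean log2 CPM of lists it was lowest in disease-associated microglia 0.709, chemokines and cytokines 0.682, lipid efflux and storage 0.663, lysosome and autophagy 0.645, oxidative stress 0.733 and neutrophil markers 0.748, and highest in AMPK and mTOR components 0.811, neuron markers 0.668 and oligodendrocyte markers 0.635. It was also lowest in the percent of counts in the top gene (0.67) and highest in the percent of mitochondrial counts (0.827).

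The other values over the limit were spread over 10 libraries. Healthy replicate 3 was lowest in Cox7a2 0.768, Cst3 0.775, Gpr34 0.641, Ndufa2 0.74, Vldlr 0.631, Xist 0.809, the respiratory complex I list 0.806, the respiratory complexes II to V list 0.705 and the ribosomal proteins list 0.629 and highest in Itgam 0.693, Man2b1 0.66, Pcna 0.805, Sall1 0.774 and Slc1a3 0.629. Healthy replicate 4 was lowest in Kdm6a 0.705, Pla2g2d 0.725, Usp9x 0.736 and the H3K27 methylation enzymes list 0.771 and highest in Cd3e 1.0 and Lat 1.0. Healthy replicate 12 was lowest in the complement list 0.812 and highest in Prx 0.712. Healthy replicate 19 was lowest in Nlrc5 0.688 and the border macrophage markers list 0.743 and highest in Cd3g 1.0 and Gclc 0.658. Control EAE replicate 1 was lowest in Cebpg 0.672, Cybb 0.688, Ddx3x 0.699, Rictor 0.824, mt-Nd5 0.706 and the mitochondrially encoded list 0.648. Control EAE replicate 2 was lowest in Il2rb 0.628. Control EAE replicate 9 was lowest in Kdm6b 0.645 and Slc7a5 0.671 and highest in Scd1 0.642. Control EAE replicate 10 was lowest in Axl 0.808, Icam1 0.629, Man2b1 0.714, Prkab1 0.691 and Slamf7 0.686 and highest in Mrc1 0.647 and Pbdc1 0.656. Metformin replicate 14 was lowest in F13a1 0.638. Metformin replicate 21 was lowest in C1ql1 0.689 and highest in Birc3 0.803 and the interferon-gamma response list 0.638.

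Metformin replicate 22 lay near the healthy libraries in disease-associated genes (93.5 on a scale from 0, control EAE, to 100, healthy) but not in interferon-gamma genes (-1.1). A control-treated healthy library under a wrong label is excluded, since its interferon-gamma score lay 15.9 healthy SDs above the healthy mean. Carry-over of RNA from 1 of the other EAE libraries into a control-treated healthy one would need like shares of the source's excess in both lists. Over 11 source libraries the median share needed was 18.38 to 135.9% for interferon-gamma genes and 0.47 to 1.26% for disease-associated genes. These values argue against such carry-over. The permutation test (largest permutation p = 8e-05) shuffled genes of 1 library, which moved together, so its p does not measure the spread between libraries. Some replicate numbers are absent from the series, so a swap with a library of a group not held here could not be tested. A mouse with mild disease or a strong response to the drug is a possible explanation, and the labels give no disease score to test it. Without this library 85.37% of EAE changes still had the opposite sign under metformin.

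Mitochondrially encoded and neuron genes were lower in EAE, and 5 of 7 and 4 of 15 rose with metformin (1 and 3 without metformin replicate 22), while the neuron score did not pass there (exact permutation adjusted p = 0.0838). Neuron markers fell more than oligodendrocyte markers in EAE, both with means (-0.622, exact permutation p = 0.00216) and with medians of markers (-0.283, exact permutation p = 0.0108). An equal fall of RNA from other spinal cord cells is not excluded, since the log2 fall of a marker also depends on its other sources of RNA. A like fall of astrocytes and either other type also stays open, as the difference of neurons and astrocytes was -0.86 with means (exact permutation p = 0.00216) and -0.073 with medians (exact permutation p = 0.732), and that of oligodendrocytes and astrocytes was -0.237 (exact permutation p = 0.00649) and 0.209 (exact permutation p = 0.139). For mitochondrially encoded genes under metformin 38.6% of the median change was left with the marker score as a covariate. That score was 1.36 in metformin replicate 22 and -0.96 to -0.27 in the other metformin libraries, so this value leans on replicate 22. A change in the amount of RNA from other cells remains a possible explanation. Loss or recovery of such RNA and a change inside microglia could both give this pattern, and these data do not separate them.

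Most respiratory chain genes and 30 of 72 ribosomal protein genes moved towards healthy levels under metformin and 0 of 15 interferon-gamma genes fell. For gene length bias, the medians (-0.45, -0.50 and -0.36 for complex I, complexes II to V and ribosomal proteins) lay below the 2.5th percentiles of random lists matched on length (-0.322, -0.316 and -0.234). Matched lists also fell, by less (-0.183, -0.189 and -0.134). Their genes were drawn singly, while genes of the 3 lists moved together (estimated correlation 0.506, 0.449 and 0.317). The range of the random lists is thus too narrow to exclude length bias as the whole cause. A milder disease state that moves all lists by the same share was tested. The shares differed, as homeostatic genes lay 73.1 points further towards healthy than interferon-gamma genes (exact permutation p = 0.00216, 6 of 6 libraries). With complex I the difference was 84.5 points (exact permutation p = 0.00216) and with ribosomal proteins 80.3 (exact permutation p = 0.00433). These lists were chosen after their changes were seen. Lists also went apart in control EAE, where replicate 10 had the highest interferon-gamma score (4.83) and the lowest disease-associated score (10.66). A milder disease state with unequal shares is not excluded, and these data do not separate it from an effect of metformin on some lists. The list calls carry little weight on their own.

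Against splits of the same 12 libraries at random, the real grouping gave the most calls of 100 in each comparison: 9932 against at most 2696 in other splits for EAE against healthy, 2703 against at most 0 for metformin against control EAE, and 6965 against at most 6237 for metformin against healthy, so 1 of 100 splits, the real one, gave as many in each. The split with 6237 exchanged metformin replicate 22 and healthy replicate 12. For lists, 1 of 100 splits gave as many calls as the real 24 for EAE against healthy (highest other 22) and 4 of 100 as many as the real 21 for metformin against healthy (highest other 21). For metformin against control EAE 29 of 100 splits gave as many list calls as the real 13 (highest other 22), so chance is not excluded for the number of lists called there.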

How the results depend on the processing

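Calls held to within 1.5-fold of the main counts (10452 for EAE against healthy, 4111 for metformin against control EAE, 6135 for metformin against healthy) with RLE, upper-quartile scaling, DESeq2, limma-voom, both filters and the numbering run as a covariate. They moved to 4534, 2519 and 2230 with the marker score as a covariate, to 4136, 579 and 1684 at 2-fold, to 1748 and 3797 at a threshold of 0.01 for the metformin comparisons, and to 2703 for metformin against control EAE with 2 groups in the fit. Chosen after seeing the data, the numbering runs alone (2 libraries per group) gave 6809, 6168 and 0 calls for EAE against healthy (6484 at an unadjusted p under 0.05 in run 3), 1967, 0 and 0 for metformin against control EAE (3089 and 2207 in runs 2 and 3), and 3312, 2582 and 0 for metformin against healthy (2060 in run 3). With 1 library left out calls ranged from 10021 to 10731, 3096 to 4272 and 4980 to 7821. Camera with an estimated correlation called 0, 0 and 0 lists (0, 0 and 7 at an unadjusted p under 0.05), fry 32, 10 and 26, and with the marker score as a covariate camera called 12 for EAE against healthy. The share of reversed EAE changes fell from 91.52 to 87.16% with split controls and to 85.37% without metformin replicate 22. With the marker score as a covariate, log2 changes in EAE against healthy turned for Cebpg (0.038), Kdm6a (0.043), Ndufab1 (0.277), Thy1 (0.042), Usp9x (0.288), Vldlr (0.430), Xist (0.157) and mt-Cytb (0.283), and for metformin against healthy for Kdm6a (0.447) and mt-Co1 (0.395). The marker score did not overlap between control EAE and healthy libraries, so its values in that comparison are extrapolated. Among metformin libraries only replicate 22 (1.36) reached the healthy range, and the others were at -0.96 to -0.27. The values with this covariate in both metformin comparisons therefore lean on that library. With library totals alone Gfap (-0.101), Prkag1 (-0.172) and Rheb (-0.221) turned in EAE, and Rpl22 for metformin against healthy was 0.000. Xist for metformin against healthy, 0.051 in the first fit, was -0.005 with upper-quartile scaling, -0.094 with library totals alone, -0.190 without healthy replicate 3 and -0.484 without metformin replicate 22 (also -0.484 without control EAE replicate 10 as well). Cd74 under metformin against control EAE was -0.128 with limma-voom and -0.030 without metformin replicate 13. With medians in place of means, marker scores turned for endothelial cells in EAE (0.212), border macrophages under metformin (0.010), oligodendrocyte precursors (0.030) and dendritic cells (-0.637) for metformin against healthy; dendritic cells in EAE (-1.579) and astrocytes for metformin against healthy (-0.616) then passed, and dendritic cells under metformin (0.942, adjusted p = 0.0506) no longer did. With 1 library left out, chosen after seeing the data, scores whose call or sign changed ranged in EAE from -0.182 to 0.205 (endothelial), 1.081 to 1.748 (Schwann), -0.163 to 0.035 (dendritic) and -1.726 to -1.13 (erythroid). Under metformin against control EAE they ranged from 0.296 to 0.607 (neuron), -0.728 to 0.007 (B and plasma), -2.252 to -0.895 (neutrophil) and -0.929 to -0.597 (border macrophage). Against healthy they ranged from -0.99 to -0.679 (neuron), -0.336 to -0.203 (astrocyte), -0.032 to 0.354 (endothelial), 1.49 to 2.124 (mural) and 0.289 to 0.488 (dendritic). The cause was not tested. No paired analysis was possible because the groups share no replicate numbers. With the numbering run as a covariate, which holds 2 libraries of each group, calls were 10693, 4602 and 6700.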

Other observations

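Trp53bp1, a DNA repair protein gene, was among the most abundant RNAs of healthy microglia here at 11000 ± 858 CPM, beside the adaptor Bcar1 at 7220 ± 794 CPM and Tubgcp4, a gamma-tubulin complex gene, at 1940 ± 151 CPM (SD, n = 6). In control EAE they were at 465 ± 191, 388 ± 134 and 125 ± 43.4 CPM, and in metformin replicate 22 at 9070, 5010 and 1680 CPM. Trp53bp1 and Tubgcp4 overlap on chromosome 2 and Bcar1 lies on chromosome 8, so overlap with these 2 genes cannot account for Bcar1. Other sources of shared reads were not tested.

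Of 678 list genes with an entry, 40 had 0 counts in all 18 libraries. They include genes that all cells use (Rps10, Rps18, Rps28, Ndufs3, Ndufa7, Uqcrc1, Atp5a1, mt-Co2, mt-Co3, mt-Atp6 and mt-Atp8) and immune genes such as Trem2, Tnf, the class II genes H2-Aa, H2-Ab1 and H2-Eb1 and the class I genes H2-K1, Tap1 and Psmb8. On chromosome 17 from 34000001 to 35000000, which holds much of the MHC region, 50 of 54 protein-coding genes (92.6%) were at 0. Cd74, whose protein partners class II molecules, was at 6440 ± 2100 CPM in control EAE, so a 0 in this table may say nothing about expression. The MHC lists rest on the 7 and 5 members tested, and the mitochondrial, respiratory chain and ribosomal lists and percentages also miss members.

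Even numbers made up 67.4 to 77.0% of counts between 1 and 99 in each library, where 50% is the share without a preference. The counting method is not given in the sources used here.

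A further question was whether the drug moved all disease genes by the same share. Disease-associated genes lay 51.0 points further towards healthy than interferon-gamma genes (exact permutation p = 0.0498, adjusted p = 0.056, 6 of 6 libraries) and 23.6 points further than type I interferon genes (exact permutation p = 0.219, 5 of 6), and neither passed after adjustment. Complex I genes lay 57.1 points further than type I interferon genes (exact permutation p = 0.00216), complexes II to V 58.2 (exact permutation p = 0.00433) and ribosomal proteins 52.9 (exact permutation p = 0.00649). These tests were chosen after the list results were seen.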
